A study of Mus musculus with 20 samples.

How the data were processed

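Poly-A RNA of microglia, the resident macrophages of the brain, was sequenced from 20 mice, per the series' description 3 animals per genotype at E16 and P15 and 4 per genotype at P60. Microglia were isolated by fluorescence-activated cell sorting, and the markers and gates of the sort are not given in the sources used here. Libraries called Control and T2MG were compared at each of the 3 stages, embryonic day 16 (E16), postnatal day 15 (P15) and postnatal day 60 (P60). Per the labels, T2MG cells could not signal through TGF-beta, a cytokine, because of their genotype; this entry is blank for P60 T2MG 4, which was grouped by its title. The series' description speaks of microglia without 1 copy or both copies of Tgfbr2, and the labels do not spell out the genotype of the Control animals. The strain entry names C57Bl6 and FVB for all 20 libraries and tells no library apart from another.

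Per the labels' protocols, RNA was purified with a Qiagen micro-scale kit, and cDNA was made with the SMART-Seq ultra low input kit of Clontech, which amplifies full-length cDNA from very little RNA. The authors deposited raw counts of reads per gene symbol, whole numbers in 1 column per library. Per the submitters' processing notes, TopHat2 (listed as version 0.7), Cufflinks 2.2.1 and the mouse build mm10 were used, with no role or order stated. The counting tool, its annotation and its treatment of strand and of reads with several matches are not given in the sources used here. Antisense and overlapping genes and near-identical paralogs are therefore uncertain. Amplified cDNA without molecular identifiers gives reads that are not independent molecules, so intervals and floors below cover counting error only.

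The table held 24421 entries, of which 27 carried a calendar date in place of a gene symbol (2 of these dates occurred more than once) and were left out; they held 0.122% to 0.256% of the counts of a library. The table had 0 symbols of mitochondrial genes, so no mitochondrial share was computed, and 0 columns without a sample. Of the other 24394 genes, 23309 had a symbol in GENCODE M21, whose GRCm38 coordinates (the same assembly as mm10) are given for genes named with a position. Replicate libraries of a group were compared by chi-square over their counts, and no pair came near sampling noise (5.3 to 152.5 per gene), so each library was counted as 1 replicate.

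In R 4.3.3, edgeR 4.0.16 was run on the counts as deposited. The default expression filter by group kept 15568 genes, libraries were scaled by TMM, and 1 group-means model over all 20 libraries and 6 groups was fitted with quasi-likelihood F tests. The common dispersion was 0.107, a biological coefficient of variation of 0.327. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Adjusted p-values of single genes come from this edgeR test unless another tool is named. Fold changes are on the log2 scale with the standard error (SE); levels are counts-per-million (CPM) on TMM-scaled library sizes, as mean ± SD over the libraries of a group. With 0 counts in a group, a fold is given as at least the ratio to a floor of 3 counts over the group; with 1 to 3 counts it is given as a ratio with its 95% interval.

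The comparisons were T2MG against Control at each stage, the differences of this genotype effect between stages, and Control libraries between consecutive stages. Gene lists were tested with camera from limma 3.58.1, which sets a list against all other genes, with a preset correlation of 0.01, adjusted over the lists of a comparison; it was repeated with an estimated correlation, and with fry, which asks whether the genes of a list move on balance in 1 direction. The 23 lists were homeostatic microglia, disease-associated microglia, interferon response, MHC class II, MHC class I, inflammatory cytokines, the TGF-beta pathway (without Tgfbr2 itself), proliferation, lysosome and phagocytosis, complement, sterol synthesis, glycolysis, immediate early genes, secreted growth factors, and markers of border-associated macrophages, monocytes, neutrophils, lymphocytes, astrocytes, neurons, oligodendrocytes, endothelial cells with pericytes, and erythroid cells. Lists needed at least 5 tested members. The disease-associated and lysosome lists shared 6 genes, and no other pair shared more than 3.

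Grouping, tests, lists, alternatives and the choice of genes to name were fixed before the data were examined. Named were Tgfbr2; for each genotype comparison the 10 highest and 10 lowest fold changes among called genes with a mean of at least 10 CPM, no overlap between the groups and an established symbol; for the other comparisons the 5 highest and 5 lowest (for differences between stages without the overlap condition); up to 4 members of each list with the smallest adjusted p; and 23 genes in every comparison, among them Tmem119, P2ry12, Sall1, Apoe, Smad7, Mrc1 and Mki67. Any other gene is said to have been chosen after its values were seen. Results of some genes are not reported here.

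The alternatives were RLE size factors, no filter beyond 1 count, a filter of at least 1 CPM in at least 3 libraries, the DESeq2 1.42.0 Wald test, limma voom, a fit of only the libraries compared, a robust fit, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were the Xist level, the neutrophil list or the neuron list as a covariate, and a fit without P60 Control 1 and P15 T2MG 3.

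Library totals were 7456271 to 9241860 counts at E16 and 12746382 to 16551240 at P15 and P60. The floor of 3 counts over a group corresponded to 0.0927 and 0.0928 CPM at E16 (Control, T2MG), 0.0647 and 0.0736 at P15, and 0.0547 and 0.0575 at P60. The steps were tested on counts simulated from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. Recovered were 36% of 2-fold and 65% of 4-fold changes at E16 (15214 genes), 36% and 70% at P15 (15275 genes), and 56% and 86% at P60 (15272 genes). Of all calls in these simulations, 1.9%, 4.5% and 6% were false.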

Results

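Reads per gene were counted for sorted microglia of 20 mice in 6 groups. Control and T2MG libraries numbered 3 each at E16, 3 each at P15 and 4 each at P60. E16 libraries were shallower than P15 and P60 libraries. The first 3 principal components of log2 CPM took 49.3%, 20.4% and 9.8% of the variance. Rn45s, a ribosomal RNA precursor, took 0.342% to 1.3% of the counts at E16 and at most 0.047% later, so differences between stages cannot be separated from differences in library making. The comparisons asked which genes differ in microglia with Tgfbr2 targeted before birth, in the juvenile and in the adult.

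Tgfbr2, the type II TGF-beta receptor (ENSMUSG00000032440, GRCm38 chromosome 9, 116084293 to 116175360, minus strand), was the targeted gene. E16 Control libraries had 196, 293 and 202 CPM and E16 T2MG libraries 165, 232 and 179 CPM. P15 Control libraries had 501, 550 and 642 CPM and P15 T2MG libraries 338, 471 and 228 CPM. P60 Control libraries had 551, 605, 649 and 581 CPM and P60 T2MG libraries 496, 647, 452 and 541 CPM. Tgfbr2 had a log2 fold change of -0.26 at E16 (SE 0.23, adjusted p 0.573), fell by 0.71 at P15 (SE 0.23, adjusted p 0.0305) and had -0.16 at P60 (SE 0.19, adjusted p 0.544). The P15 call ended without Control 2 (adjusted p 0.0581), Control 3 (0.116), T2MG 1 (0.0699) or T2MG 3 (0.132). Counts cover the whole gene and the deleted part is not given in the sources used here, so this gene checks the genotype labels only weakly. Smad7, an inhibitor that TGF-beta signalling induces (chromosome 18, 75367529 to 75395935), had -1.43 at E16 (adjusted p 0.0573), which passed the test without E16 Control 3 (-1.55, adjusted p 0.0439). It fell by 4.48 at P15 (SE 0.43, adjusted p 2.39e-06), from 204 ± 14.1 to 9.08 ± 5.71 CPM. At P60 Smad7 fell by 5.05 (SE 0.39, adjusted p 2.44e-08), from 183 ± 13.5 to 5.52 ± 1.86 CPM.

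**Figure D1:**
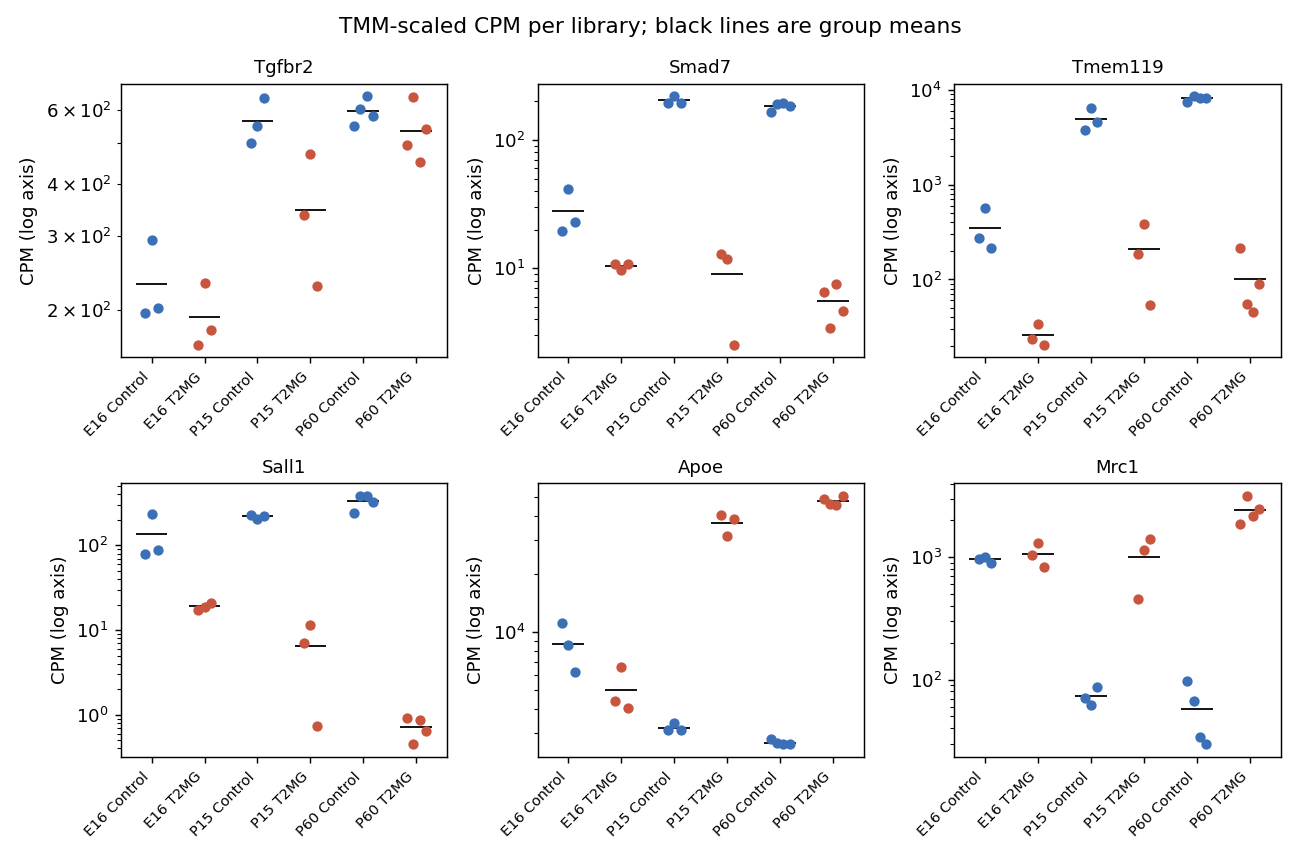
Level of Tgfbr2, Smad7, Tmem119, Sall1, Apoe and Mrc1 in each library, in CPM on a log axis, for Control (blue) and T2MG (red) at E16, P15 and P60, with points for libraries and black lines for group means. Tgfbr2 lies between 165 and 649 CPM in all 20 libraries, while the group mean of Apoe at P15 is 3210 CPM in Control and 36600 CPM in T2MG.

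At E16, genes that mark microglia were lower in T2MG. Olfml3, a secreted glycoprotein (chromosome 3, 103722222 to 103738001), fell by 5.59 on the log2 scale (adjusted p 0.00175), from 327 ± 171 to 6.79 ± 1.34 CPM (SD, 3 libraries per group). Tmem119, a microglial membrane protein (chromosome 5, 113793729 to 113800516), fell by 3.75 (adjusted p 0.00324), from 350 ± 186 to 26 ± 6.81 CPM. Mmp13, a collagenase (chromosome 9, 7272514 to 7283331), rose by 5.82 (SE 0.84, adjusted p 0.000926), from 0.779 ± 0.456 to 44.3 ± 16 CPM. Spic, a transcription factor of iron-recycling macrophages, rose by 4.79 (SE 0.61, adjusted p 4e-04), from 1.67 ± 0.884 to 45.7 ± 16.4 CPM. Of 15568 genes, 82 were called higher and 416 lower in T2MG, 498 in all. At least a 2-fold change was seen for 239 of them, and 2688 genes had an unadjusted p under 0.05.

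Other large rises at E16 were those of the metalloprotease Adamdec1 (5.77, adjusted p 0.000926), the adhesion molecule Vcam1 (4.11, adjusted p 0.00256) and the adhesion receptor Adgrl3 (3.06, adjusted p 0.00191). Other large falls were those of the protease inhibitor Spint1 (-4.15, adjusted p 0.000791), the fatty acid receptor Gpr84 (-3.98, adjusted p 4.81e-05) and the fructose transporter Slc2a5 (-3.93, adjusted p 0.00296). These genes were chosen among those whose groups did not overlap, which chance gives for 10% of genes with 3 against 3 libraries.

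Of 37 homeostatic microglia genes, 24 fell at E16 (29 adjusted over the list alone) and the rest were not called. The list median was -1.49 (camera adjusted p 1.04e-42, and adjusted p = 0.0476 with an estimated correlation). Selplg (-1.54, adjusted p 0.000489) and Cd33 (-1.62, adjusted p 0.00079) were among those that fell. Sall1, a transcription factor of microglial identity (chromosome 8, 89027235 to 89044162), fell by 2.82 (adjusted p 0.0063), a call that ended without E16 Control 2 (-2.13, adjusted p 0.0527). Median levels of the list were 175, 306 and 163 CPM in Control and 73.9, 80.7 and 68.5 CPM in T2MG libraries. Cx3cr1 (-1.11, adjusted p 0.324) and Csf1r (-0.58, adjusted p 0.326) were not called. In the same libraries the neuron list had medians of 13.9, 16.5 and 31.7 CPM (Control) and 52.7, 37.8 and 36.2 CPM (T2MG).

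Of 30 disease-associated microglia genes, which rise in microglia near amyloid plaques, 8 fell at E16 (12 adjusted over the list alone). Their median was -0.68 (camera adjusted p 4.41e-13, and adjusted p = 0.0519 with an estimated correlation). Spp1, or osteopontin (-3.34, adjusted p 0.00177), fell from 104 ± 22.9 to 10.3 ± 2.38 CPM, and Cd9 (-2.54, adjusted p 0.000791) and the lipid receptor Trem2 (-3.04, adjusted p 0.00202) also fell. Apoe, a lipid carrier, had -0.79 (adjusted p 0.0746), which passed the test without E16 Control 3 (-0.97, adjusted p 0.0171) or T2MG 2 (-1.03, adjusted p 0.0352). Of 26 lysosomal genes, 10 fell (14 adjusted over the list alone), among them the proteases Ctss (-1.69, adjusted p 0.00119) and Ctsd (-1.78, adjusted p 0.00244). The lysosomal median was -0.57 (camera adjusted p 7.42e-15, and adjusted p = 0.0896 with an estimated correlation). Among 26 inflammatory genes, the cytokine Il1a (-2.63, adjusted p 0.00155) and the chemokines Ccl4 (-2, adjusted p 0.00296) and Ccl3 (-1.72, adjusted p 0.022) fell (5 adjusted over the list alone). Their median was -0.38, or -0.45 without 2 members that had at most 3 counts in each group (camera adjusted p 0.00113, and adjusted p = 0.188 with an estimated correlation). Among 13 complement genes, the receptor subunit Itgam (-1.28, adjusted p 0.00496) and C1qa (-0.98, adjusted p 0.0323) fell (6 adjusted over the list alone). The complement median was -0.47 (camera adjusted p 0.000966, and adjusted p = 0.115 with an estimated correlation). The calls of Ccl3 and C1qa ended without E16 Control 1 (adjusted p 0.0532 and 0.15), Control 2 (0.107 and 0.181), T2MG 1 (0.0806 and 0.146) or T2MG 3 (0.0512 and 0.17), and that of Ccl3 without T2MG 2 (0.0987).

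Metabolic, immediate early and growth factor lists also moved at E16. Among 17 glycolysis genes, hexokinase Hk2 (-1.24, adjusted p 0.00126), the lactate exporter Slc16a3 (-1.17, adjusted p 0.00735) and Aldoa (-0.74, adjusted p 0.0213) fell (5 adjusted over the list alone). Their median was -0.38 (camera adjusted p 1.47e-05, and adjusted p = 0.2 with an estimated correlation). Klf2 (-1.57), Atf3 (-1.67) and Jun (-1.11) fell among 20 immediate early genes (6 adjusted over the list alone), which also respond to cell dissociation. The median of that list was -0.77 (camera adjusted p 5.53e-08, and adjusted p = 0.2 with an estimated correlation). Spp1, Csf1 (-1.77) and Vegfb (-0.74) fell among 14 secreted growth factors (3 adjusted over the list alone). The growth factor median was -0.39 (camera adjusted p 0.0163, and adjusted p = 0.2 with an estimated correlation). Acat2 (0.78) rose among 21 sterol synthesis genes (5 adjusted over the list alone), whose median was 0.36 (camera adjusted p 0.000119, and adjusted p = 0.2 with an estimated correlation). Calls of Aldoa, Klf2, Atf3, Jun, Csf1, Vegfb and Acat2 each ended without at least 3 of the E16 libraries other than Control 3, with adjusted p of up to 0.253 for Acat2 without Control 1, 0.187 for Acat2 without Control 2, 0.101 for Acat2 without T2MG 1, 0.151 for Jun without T2MG 2 and 0.123 for Acat2 without T2MG 3. The growth factor list was not called without Control 3 (adjusted p 0.0901) or T2MG 2 (0.0951), or with no filter beyond 1 count (-0.15, 0.0778).

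Markers of neurons and astrocytes were higher as lists in E16 T2MG libraries. Of 17 neuron markers, edgeR called 0, with 5 at an unadjusted p under 0.05, 3 called by DESeq2 and 8 by limma voom (3 higher adjusted over the list alone). Their median was 0.98 (camera adjusted p 3.97e-05, and adjusted p = 0.2 with an estimated correlation). Map2, a neuronal cytoskeleton protein, had 1.41 (adjusted p 0.0556), which passed the test without E16 Control 3 (1.89, adjusted p 0.0123). Of 14 astrocyte markers, edgeR called 0 (also 0 adjusted over the list alone), with 6 at an unadjusted p under 0.05, 1 called by DESeq2 and 3 by limma voom. The astrocyte median was 1.07, or 1.01 without 1 member at or under the floor of 3 counts in both groups (camera adjusted p 3.97e-05, and adjusted p = 0.2 with an estimated correlation), and the list was not called with the neuron list as a covariate (0.41, adjusted p 0.0512). Of 10 MHC class II genes edgeR called 0 (also 0 adjusted over the list alone), with 3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom. Class II had a median of -0.55 (camera adjusted p 0.0131, and adjusted p = 0.512 with an estimated correlation) and was not called without E16 T2MG 2 (adjusted p 0.129). Of 12 MHC class I genes edgeR called 0 (also 0 adjusted over the list alone), with 3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom. Class I had a median of -0.54 (camera adjusted p 0.00756, and adjusted p = 0.512 with an estimated correlation) and was not called without E16 Control 1 (adjusted p 0.196).

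The remaining lists did not pass the camera test at E16. Among 31 TGF-beta pathway genes (median -0.01, or 0 without 1 member at or under the floor in both groups, adjusted p 0.563), the type I receptor Tgfbr1 (-1.33, adjusted p 0.0213) and Pmepa1 (-2.12, adjusted p 0.0366) fell (3 adjusted over the list alone). Both calls ended without E16 Control 2 (-0.73, adjusted p 0.152, and -1.68, 0.188), T2MG 1 (0.1 and 0.11) or T2MG 3 (0.101 and 0.154), and that of Pmepa1 without Control 1 (0.0742) or T2MG 2 (0.119). Among 32 proliferation genes (median -0.17, adjusted p 0.24), Mcm3 fell (-0.6, adjusted p 0.035, 1 adjusted over the list alone), but not without Control 1 (0.129), Control 2 (0.182), T2MG 1 (0.155) or T2MG 2 (0.148). Csf3r, a neutrophil cytokine receptor, fell (-1.47, adjusted p 0.000997) among 11 neutrophil markers (median -0.52, adjusted p 0.378), where 1 gene was higher and 1 lower adjusted over the list alone. Interferon response genes (30, median -0.37, adjusted p 0.156), border-associated macrophages (20, -0.13, 0.824), monocytes (15, -0.7, 0.275) and lymphocytes (17, 0, 0.777) had 0 members called by edgeR and 0 adjusted over the list alone. At an unadjusted p under 0.05 they had 0, 2, 0 and 1 members, with 0, 2, 0 and 0 called by DESeq2 and 0, 2, 0 and 1 by limma voom. Oligodendrocyte (13, 0.45, adjusted p 0.288), endothelial (17, 0.58, 0.137) and erythroid markers (7, 0.4, 0.563) also had 0 members called by edgeR and 0 adjusted over the list alone. Unadjusted they had 2, 1 and 0 members, with 0, 0 and 0 called by DESeq2 and 0, 1 and 0 by limma voom. Without members at or under the floor in both groups (5 and 1), the lymphocyte median was -0.03 and the oligodendrocyte median 0.67. The lymphocyte mean was 0.02 while its test pointed down. Monocyte and neutrophil lists were called without E16 Control 2 (adjusted p 0.0291 for both), and the interferon list without Control 2 (0.00108), Control 3 (0.048) or T2MG 3 (0.00674). Mrc1, the mannose receptor, had 0.15 (adjusted p 0.88), with 1070 ± 243 CPM in T2MG and 960 ± 53.9 CPM in Control.

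The number of genes called at E16 was 204, 148 and 961 without Control 1, 2 and 3, and 204, 270 and 192 without T2MG 1, 2 and 3. DESeq2 called 986 (339 higher, 647 lower), limma voom 1198 (715 higher, 483 lower), a fit of only the E16 libraries 319 and a fit with the neuron list as a covariate 125.

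At P15, Apoe, Mmp13 and macrophage genes were higher in T2MG and microglial markers were much lower. Apoe (chromosome 7, 19696109 to 19699188) rose by 3.51 (SE 0.25, adjusted p 2.47e-07), from 3210 ± 167 to 36600 ± 4690 CPM (SD, 3 libraries per group). It took 2.92% to 3.48% of the counts of T2MG libraries and 0.3% to 0.32% of Control libraries. Mmp13 rose by 9.58 (SE 0.91, adjusted p 2.21e-06), from 0.9 ± 0.253 to 699 ± 300 CPM. Mrc1 (chromosome 2, 14229392 to 14332057) rose by 3.78 (SE 0.45, adjusted p 1.37e-05), from 73.5 ± 12.8 to 1010 ± 498 CPM. Siglech, a lectin of microglia, fell by 4.42 (adjusted p 8.65e-05), or by 5.24 without T2MG 2, from 869 ± 171 to 40.4 ± 33.4 CPM. Of 15568 genes, 1821 were called higher and 1917 lower, 3738 in all. Of these 2108 changed at least 2-fold, and 5709 genes had an unadjusted p under 0.05.

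Clec4n, a C-type lectin (6.1, adjusted p 2.92e-05), rose from 8.91 ± 3.23 to 612 ± 143 CPM at P15. BC018473 had the highest fold (10.54, adjusted p 0.000166, and 11.43 without P15 Control 3), but it is annotated as antisense (chromosome 11, 116752167 to 116759373) and its reads cannot be told from those of the other strand. The rises of Gdf15 (6.94), the decoy receptor Il1r2 (5.86) and BC100530 (7.49) were 5.05, 2.73 and 4.13 without P15 T2MG 3. Tmem204 (-5.93, SE 0.35, adjusted p 2.35e-08) fell from 43.4 ± 2.7 to 0.687 ± 0.455 CPM, and the crystallin Crybb1 (-5.59, adjusted p 7.29e-06) from 170 ± 9.28 to 3.49 ± 1.96 CPM. Sall1 fell by 5.07 (adjusted p 1.3e-05), or to -5.79 without T2MG 2, and Tmem119 fell by 4.56 (adjusted p 0.000103), or to -5.35 without T2MG 2.

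Of 37 homeostatic genes, 35 fell at P15 and 1 rose (36 and 1 adjusted over the list alone). The list median was -3 (camera adjusted p 2.97e-37, and adjusted p = 0.03 with an estimated correlation). Selplg (-2.52, adjusted p 7.91e-07), the adhesion receptor Adgrg1 (-4.56, adjusted p 2.39e-06) and the fractalkine receptor Cx3cr1 (-3.68, adjusted p 0.000382) fell. The chemokine Ccl12 rose (2.1, adjusted p 6.99e-05) and Mertk was not called (-0.85, and -1.27, adjusted p 0.015, without P15 T2MG 3), both chosen after their values were seen. Of 30 disease-associated genes, 15 rose and 5 fell (17 and 5 adjusted over the list alone), with a median of 1.23 (camera adjusted p 2.63e-05, and adjusted p = 0.319 with an estimated correlation). The receptor kinase Axl (3.39, SE 0.53, adjusted p 0.000191) rose from 173 ± 6.8 to 1820 ± 649 CPM, and the protease Ctsb (1.5, adjusted p 0.000166) and Spp1 (2.24, adjusted p 0.00361) also rose. Those that fell were Csf1 (-1.22, adjusted p 0.0173) and, chosen after their values were seen, Cd9 (-2.16), Ctsd (-1.78), Ctsl (-1.48) and Trem2 (-3.13). Itgax (0.45, adjusted p 0.413) and Cst7 (0.83, adjusted p 0.298) were not called.

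Of 31 TGF-beta pathway genes, 14 fell and 4 rose at P15 (15 and 4 adjusted over the list alone), with a median of -0.91 (camera adjusted p 6.18e-06, and adjusted p = 0.00625 with an estimated correlation). Tgfbr1 (-3, adjusted p 5.75e-06) fell from 1040 ± 88.1 to 130 ± 42.4 CPM, and the SMAD repressor Skil (-2.58, adjusted p 1.7e-05) and the signal transducer Smad3 (-1.83, adjusted p 2.83e-05) fell with Smad7. Tgfb3 (3.37), Nrros (0.84), Acvrl1 (1.16) and Tgfbi (1.78) rose and were chosen after their values were seen, and the calls of Tgfb3 and Tgfbi ended without P15 T2MG 3 (1.64, adjusted p 0.0575, and 1.19, 0.0713).

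Of 20 border-associated macrophage genes, which mark macrophages of meninges and vessels, 13 rose at P15 (14 adjusted over the list alone) and the rest were not called. Their median was 2.69, or 2.04 without T2MG 2 and 1.7 with the neuron list as a covariate (camera adjusted p 7.21e-09, and adjusted p = 0.319 with an estimated correlation). Mrc1, Clec4n and the copper oxidase Cp (2.56, adjusted p 1.37e-05) were among them. Median levels were 205, 231 and 200 CPM in T2MG and 20.3, 20.2 and 16.4 CPM in Control libraries. Vcan (4.57) and Gsr (1.95, adjusted p 0.0209) rose among 15 monocyte markers (2 adjusted over the list alone), whose median was 1.62 (camera adjusted p 0.033, and adjusted p = 0.703 with an estimated correlation). Vcan had 5.5 without Control 1 and 2.62 without T2MG 3, and the call of Gsr ended without Control 1 (adjusted p 0.0587), Control 2 (0.074), Control 3 (0.0569) or T2MG 3 (0.96, 0.215). The monocyte list was not called without Control 2 (adjusted p 0.0581) or T2MG 3 (0.87, 0.106), nor with the neuron list (median -0.66, test upwards, 0.681) or the neutrophil list (-0.08, test upwards, 0.871) as a covariate. Among 17 neuron markers, Tubb3 (2.09, adjusted p 0.00549), Rbfox3 (2.31), Snap25 (2.07) and Map2 (1.26) rose (8 adjusted over the list alone). The neuron median was 2.07, or 1.64 with Dcx at its bound, 1.43 without T2MG 2 and 1.4 with the neutrophil covariate (camera adjusted p 0.00119, and adjusted p = 0.596 with an estimated correlation). Calls of Rbfox3, Snap25 and Map2 ended without Control 1 (adjusted p 0.0881, 0.107 and 0.169), Control 3 (0.106, 0.101 and 0.0756) or T2MG 3 (0.101, 0.0985 and 0.176). Without Control 2, Rbfox3 had 3.96, Snap25 2.8 and Map2 lost its call (0.0839), as it did without T2MG 2 (0.11).

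Among 30 interferon response genes, Oas2 (2.11, adjusted p 0.00771), Bst2 (1.21, adjusted p 0.0138) and Ifi204 (1.53, adjusted p 0.0144) rose at P15 (3 adjusted over the list alone). Their median was 0.85 (camera adjusted p 0.0297, and adjusted p = 0.746 with an estimated correlation). H2-D1 (0.98), H2-K1 (1.13) and H2-M3 (0.79) rose among 12 MHC class I genes (3 adjusted over the list alone), whose median was 0.57 (camera adjusted p 0.0368, and adjusted p = 0.703 with an estimated correlation). Both lists were not called without P15 Control 2 (adjusted p 0.105 and 0.0781), T2MG 1 (0.375 and 0.171) or T2MG 2 (0.142 and 0.0819). The call of Oas2 ended without T2MG 1 (adjusted p 0.0544), that of Bst2 without Control 2 (0.0589) or T2MG 1 (0.0734) and that of Ifi204 without Control 1 (0.0511) or Control 2 (0.0673). Calls of H2-D1, H2-K1 and H2-M3 ended without Control 1 (adjusted p 0.162, 0.0789 and 0.101), Control 2 (0.0965, 0.149 and 0.0887), Control 3 (0.0525, 0.11 and 0.0594) or T2MG 1 (0.0658, 0.164 and 0.0844). Those of H2-K1 and H2-M3 also ended without T2MG 2 (0.081 and 0.0731), and that of H2-D1 without T2MG 3 (0.149). The cell cycle regulator E2f1 (1.54, adjusted p 0.00304), Stmn1 (1.09) and Tyms (0.82) rose among 32 proliferation genes (1 adjusted over the list alone), whose median was 0.65 (camera adjusted p 0.00169, and adjusted p = 0.703 with an estimated correlation). Stmn1 and Tyms lost their calls without Control 2 (adjusted p 0.104 and 0.108), Control 3 (0.125 and 0.13), T2MG 1 (0.0584 and 0.0827) or T2MG 3 (0.148 and 0.111), and Tyms without Control 1 (0.0574). Of 20 immediate early genes, 6 fell, among them Btg2 (-1.5, adjusted p 6.07e-05), with 7 lower and 1 higher adjusted over the list alone. Their median was -0.6 (camera adjusted p 0.0114, and adjusted p = 0.703 with an estimated correlation), and the list was not called without Control 2 (adjusted p 0.0547) or T2MG 2 (0.142). With the neutrophil covariate the interferon (0.36, adjusted p 0.264), MHC class I (0.31, 0.186) and proliferation lists (0.06, 0.303) were not called, nor with the neuron covariate the MHC class I (0.46, 0.0621), proliferation (0.02, 0.252) and immediate early lists (-0.67, 0.0621).

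The other lists did not pass the camera test at P15. Of 10 MHC class II genes (median 2.1, adjusted p 0.0853, and 0.00222 without P15 T2MG 3), 7 rose and 2 fell (8 and 2 adjusted over the list alone). Cd74, the invariant chain (3.17, adjusted p 0.00549), rose from 2820 ± 729 to 25300 ± 12600 CPM, while H2-Oa (-2.8) and H2-Ob (-3.57, and -4.82 without T2MG 2) fell. Of 26 inflammatory genes (median 0.13, adjusted p 0.208), 6 rose and 2 fell (6 and 2 adjusted over the list alone). Cxcl16 (2.86, adjusted p 3.25e-05) and the cytokine Il1b (1.95, adjusted p 0.00371) rose, and Il1a (-1.9, adjusted p 0.00121) and, chosen after its value was seen, Il6 (-1.8) fell, the latter not without Control 2 (adjusted p 0.0691) or T2MG 3 (0.0618). Of 26 lysosomal genes (median 0.31, adjusted p 0.0823, and 0.0403 without T2MG 1), 9 rose and 5 fell (10 and 6 adjusted over the list alone). The scavenger receptor Msr1 rose (3.46, adjusted p 5.86e-05), and Pros1, Ctsd, Ctsl and Ctss, chosen after their values were seen, fell. Of 13 complement genes (median 0.46, adjusted p 0.0823), 3 rose and 2 fell (4 and 2 adjusted over the list alone). Properdin Cfp (4.46, adjusted p 0.000166), C5ar1 (2.06) and C4b (2.9) rose, and Itgam (-1.54, adjusted p 0.000147) fell.

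Of 21 sterol genes at P15 (median 0.03, adjusted p 0.726), Mvk (1.08), Dhcr7 (0.83) and Pmvk (0.54) rose and Hmgcs1 (-0.93) fell (3 and 1 adjusted over the list alone). The call of Pmvk ended without Control 1 (adjusted p 0.101), Control 2 (0.107), Control 3 (0.0813), T2MG 1 (0.0527) or T2MG 3 (0.169). Of 17 glycolysis genes (median 0.13, mean -0.09, test upwards, adjusted p 0.789), 5 rose and 2 fell (5 and 2 adjusted over the list alone). Pkm (0.91), Ldha (0.71) and, chosen after their values were seen, Gapdh (0.6), Tpi1 (0.46) and Gpi1 (1.1) rose. Without T2MG 3 the calls of Pkm (adjusted p 0.0512), Gapdh (0.147), Tpi1 (0.121) and Gpi1 (0.0602) ended. Those of Gapdh, Tpi1 and Gpi1 also ended without Control 2 (0.15, 0.116 and 0.0504), those of Gapdh and Tpi1 without Control 1 (0.0752 and 0.0623), and that of Gapdh without Control 3 (0.0961) or T2MG 1 (0.105). Hk2 (-1.72, adjusted p 8.43e-06) and Pfkfb3 (-1.19, and -1.78 without T2MG 3) fell. Of 14 growth factors (median 0.2, adjusted p 0.231, and 0.0208 without T2MG 3), 4 rose and 2 fell (4 and 2 adjusted over the list alone). Igf1 (3.53, and 2.61 without T2MG 2), Spp1, Bmp2 (2.35) and, chosen after its value was seen, Gas6 (0.83) rose. Csf1 and, chosen likewise, Pdgfa (-0.93) fell. Calls of Gas6 and Pdgfa ended without Control 1 (adjusted p 0.0977 and 0.0534), Control 2 (0.0534 and 0.137) or T2MG 2 (0.0772 and 0.0728), that of Gas6 without T2MG 1 (0.0591) and that of Pdgfa without Control 3 (0.0823) or T2MG 3 (0.155). Bmp2 had 3.15 without Control 2 and lost its call without Control 1 (adjusted p 0.0695), Control 3 (0.0821) or T2MG 2 (0.0662).

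Among 11 neutrophil markers at P15 (median 2.13, adjusted p 0.055), Cxcr2 (2.91), Mmp9 (4.17) and Mmp8 (3.66) rose, with 4 higher and 1 lower adjusted over the list alone. Cxcr2 had 3.64 without Control 1 and 1.96 without T2MG 3, Mmp9 lost its call without Control 3 (adjusted p 0.0623), and Mmp8 lost its call without Control 1 (0.0997), Control 2 (0.112), Control 3 (0.146) or T2MG 3 (0.236). The neutrophil list was called without Control 1 (0.031) or T2MG 2 (0.0184), and its median level was 1940, 484 and 1770 CPM in T2MG and 384, 497 and 242 CPM in Control libraries. Cd4 (4.65, adjusted p 0.00239, and 5.45 without Control 1) rose among 17 lymphocyte markers (median 1.05, adjusted p 0.172, 1 adjusted over the list alone). Among 14 astrocyte markers (median 0.38, adjusted p 0.667), Gfap (2.78, adjusted p 0.00125) and Slc1a2 (1.57) rose and the glutamate transporter Slc1a3 (-2.35, adjusted p 0.000114) and Sox9 (-1.95) fell (2 and 2 adjusted over the list alone). Slc1a2 and Sox9 lost their calls without Control 1 (adjusted p 0.126 and 0.0707), Control 3 (0.0905 and 0.147) or T2MG 3 (0.209 and 0.149), and Sox9 without T2MG 2 (0.0868). Among 13 oligodendrocyte markers (median 0.84, adjusted p 0.196), the myelin proteins Mbp (1.78, adjusted p 0.000795) and Mobp (1.74) rose and Cspg4 (-4.66) fell (3 and 1 adjusted over the list alone). Mobp lost its call without Control 1 (0.0853), Control 3 (0.0689) or T2MG 3 (0.0639). Among 17 endothelial markers (median 0.16, mean -0.49, test downwards, adjusted p 0.575), Ly6c1 (-3.39) and Slco1a4 (-2.46) fell (2 adjusted over the list alone). Ly6c1 lost its call without Control 1 (-2.66, 0.0778), and Slco1a4 without Control 3 (0.0685), T2MG 1 (0.0539) or T2MG 3 (0.0785). Of 7 erythroid genes (median 0, mean -0.01, test upwards, adjusted p 0.789), edgeR called 0, as did DESeq2 and limma voom, with 0 adjusted over the list alone and 0 at an unadjusted p under 0.05.

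The number of genes called at P15 was 2470 without P15 Control 3, 2209 in a fit of only the P15 libraries and 2395 with the neuron list as a covariate.

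At P60, T2MG libraries had almost no Sall1 and high levels of Apoe, Mrc1 and Il10. Sall1 fell by 8.83 (SE 0.64, adjusted p 1.35e-08), from 333 ± 66.1 to 0.716 ± 0.214 CPM (SD, 4 libraries per group). The purinergic receptor P2ry12 fell by 6.18 (SE 0.51, adjusted p 5.39e-08), from 11900 ± 3110 to 165 ± 35.4 CPM. Apoe rose by 4.15 (SE 0.23, adjusted p 7.49e-10), from 2690 ± 86.8 to 47600 ± 2500 CPM, and took 3.87% to 4.4% of T2MG and 0.22% to 0.25% of Control counts. The anti-inflammatory cytokine Il10 rose by 8.87 (SE 0.4, adjusted p 1.57e-10), from 0.32 ± 0.196 to 157 ± 32.3 CPM, and Mrc1 by 5.41 (SE 0.42, adjusted p 2.5e-08), from 57.1 ± 31.6 to 2430 ± 561 CPM. Of 15568 genes, 3666 were called higher and 2447 lower, 6113 in all. Of these 3665 changed at least 2-fold, and 7443 genes had an unadjusted p under 0.05. The median log2 fold change of all genes was 0.137 (0.071 with RLE size factors).

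Ifi202b (9.2, adjusted p 2.45e-05) and the scavenger receptor Marco (8.46, SE 0.91, adjusted p 1.08e-06) were among the largest rises at P60. Mrap, a melanocortin receptor accessory protein, was higher by a ratio of 1190 (95% interval 329 to 9840), with a fitted log2 fold change of 9.89, or 12.13 without P60 Control 1. Mmp13 (8.51), Clec4n (8), Cxcl1 (7.79), Spic (7.72), Lbx1 (7.7) and C6 (7.67) rose by 10.47, 9.54, 8.88, 9.3, 9.24 and 11.65 without P60 Control 1. The coagulation factor F9 was at least 430-fold lower, and Adamts16 was lower by a ratio of 435 (95% interval 149 to 2110), with a fitted log2 fold change of -8.56, or -11.36 without P60 T2MG 3.

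Of 37 homeostatic genes, 35 fell at P60 and 1 rose (35 and 1 adjusted over the list alone). The list median was -3.27 (camera adjusted p 1.73e-38, and adjusted p = 0.0318 with an estimated correlation). Selplg (-4.26, adjusted p 1.57e-10) fell from 7240 ± 725 to 379 ± 27.5 CPM, and the matrix protein Sparc (-6.09, adjusted p 8.57e-09) from 6590 ± 2120 to 97 ± 37.5 CPM. Adgrg1 (-6.75, adjusted p 3.41e-09), Cx3cr1 (-3.02, adjusted p 0.000188) and Csf1r (-0.96, adjusted p 0.00633) also fell. Ccl12, chosen after its value was seen, rose (3, adjusted p 9.54e-08). Of 31 TGF-beta pathway genes, 15 fell and 10 rose (15 and 11 adjusted over the list alone), with a median of -0.24 (camera adjusted p 0.000388, and adjusted p = 0.0318 with an estimated correlation). Tgfbr1 (-3.93, adjusted p 1.35e-08) fell from 1660 ± 162 to 109 ± 16.6 CPM, and Smad3 (-2.24, adjusted p 1.52e-07) and the SMAD repressor Ski (-3.3, adjusted p 5.3e-07) fell too.

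Of 20 border-associated macrophage genes, 19 rose at P60 (19 adjusted over the list alone), all but Ccr1 (0.12, adjusted p 0.819), chosen after its value was seen. Their median was 5.1, or 6.35 without P60 Control 1 and 3.86 with the neuron covariate (camera adjusted p 1.82e-14, and adjusted p = 0.045 with an estimated correlation). Cp (5.19, SE 0.29, adjusted p 9.57e-10) rose from 14.4 ± 3.59 to 525 ± 89.9 CPM, and the lectin Siglec1 (6.51, adjusted p 2.56e-07) from 2.65 ± 1.46 to 245 ± 61.2 CPM. Median levels were 553, 604, 686 and 613 CPM in T2MG and 29.1, 3.34, 2.64 and 3.08 CPM in Control libraries. Of 30 interferon response genes, 28 rose (29 adjusted over the list alone), with a median of 2.12 (camera adjusted p 5.9e-08, and adjusted p = 0.547 with an estimated correlation). Ifi204 (3.45, adjusted p 2.44e-06) and Bst2 (2.18, adjusted p 1.57e-05) were among them, and Oas3 (1.46, adjusted p 0.16), chosen after its value was seen, was not called. Without P60 Control 1 it was (adjusted p 0.000781). Of 12 MHC class I genes, 7 rose (7 adjusted over the list alone), among them H2-D1 (2.55, adjusted p 3.74e-06), with a median of 0.87 (camera adjusted p 0.00203, and adjusted p = 0.547 with an estimated correlation). Of 32 proliferation genes, 24 rose (28 adjusted over the list alone), with a median of 1.42, or 2.7 without P60 Control 1 and 0.62 with the neuron covariate (camera adjusted p 1.7e-05, and adjusted p = 0.633 with an estimated correlation). E2f1 rose by 2.96 (adjusted p 8.38e-07) and the cycling marker Mki67 by 2.4 (adjusted p 0.00209), or 3.53 without P60 Control 1. Of 26 inflammatory genes, 15 rose and 2 fell (17 and 2 adjusted over the list alone). Their median was 0.88, or 0.92 without 1 member at or under the floor in both groups (camera adjusted p 0.000641, and adjusted p = 0.11 with an estimated correlation). Il1b rose by 4.34 (adjusted p 4.13e-07), or 4.97 without P60 Control 1, and the NF-kappaB inhibitor Tnfaip3 by 1.88 (adjusted p 1.55e-06), while Il1a and Icam1 (-0.53), chosen after their values were seen, fell. The call of Icam1 ended without Control 4 (adjusted p 0.0569) or T2MG 1 (0.0618).

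Markers of other brain cells were also higher at P60. Of 13 oligodendrocyte markers, 12 rose (13 adjusted over the list alone), with a median of 2.82, or 1.8 with the neuron covariate (camera adjusted p 0.000109, and adjusted p = 0.268 with an estimated correlation). Mbp (2.59, adjusted p 2e-06) rose from 108 ± 31.8 to 650 ± 238 CPM. Median levels of this list were 23.6, 15.5, 10.3 and 21.7 CPM in T2MG and 2.36, 1.28, 4.71 and 2.4 CPM in Control libraries. Of 14 astrocyte markers, 13 rose (13 adjusted over the list alone), among them Gja1 (3.14) and Slc1a2 (2.71), while Slc1a3 fell (-2.5, adjusted p 3.99e-06, 1 adjusted over the list alone). The astrocyte median was 2.42, or 3.21 without P60 Control 1 (camera adjusted p 0.00227, and adjusted p = 0.547 with an estimated correlation), and with the neuron covariate the list was not called (0.63, adjusted p 0.46). Of 17 neuron markers, 10 rose (11 adjusted over the list alone), with a median of 2.02, or 3.22 without that library (camera adjusted p 0.0015, and adjusted p = 0.547 with an estimated correlation). Nefl (3.48) and Map2 (3.12, adjusted p 9.92e-05) were among them. Neuron list levels were 3.31, 1.96, 2.18 and 1.87 CPM in T2MG and 0.97, 0.284, 0.29 and 0.32 CPM in Control libraries.

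The other lists did not pass the camera test at P60. Of 30 disease-associated genes (median 0.77, adjusted p 0.13, and 0.00405 without P60 Control 1), 15 rose and 7 fell (17 and 7 adjusted over the list alone). The growth factor Igf1 (5.15, adjusted p 1.48e-07) and the lipase Lpl (3.64, adjusted p 0.000143) rose, and Cst7 fell (-3.04, adjusted p 0.000269, and -4.18 without T2MG 1). Itgax (0.48, adjusted p 0.264) and Spp1 (-0.16, adjusted p 0.792) were not called. Of 10 MHC class II genes (median 1.28, or 2.22 and 0.67 without P60 Control 1 and T2MG 3, adjusted p 0.818), 3 rose and 2 fell (3 and 2 adjusted over the list alone). Cd74 (2.34, and 3.59 without P60 Control 1), H2-DMb2 (1.85) and, chosen after its value was seen, Ciita (2.83, and 3.63 without that library) rose, and H2-Oa (-4.08, and -4.97 without T2MG 1) and H2-Ob (-3.21) fell. Of 26 lysosomal genes (median 0.31, adjusted p 0.69), 12 rose and 6 fell (12 and 6 adjusted over the list alone), among the latter Ctsd (-3.29, adjusted p 5.12e-08) and Ctss (-2.06, adjusted p 1.23e-06). Of 13 complement genes (median 0.36, or 1.53 without Control 1, adjusted p 0.295), 5 rose and 2 fell (5 and 2 adjusted over the list alone). C3ar1 (1.37), C5ar1 (2.65), Cfp (6.7, and 8.02 without P60 Control 1) and, chosen after their values were seen, C4b (2.89, and 3.96 without Control 1) and Cfb (2.68, and 2.07 without T2MG 4) rose. Itgam (-3.16, adjusted p 6.8e-09) fell. Of 21 sterol genes (median -0.08, or 0.36 without Control 1, adjusted p 0.699), Mvk (0.86), Dhcr7 (0.58) and, chosen after its value was seen, Pmvk (0.45) rose, and Sc5d (-1.56), Msmo1 (-0.77) and, chosen likewise, Fdft1 fell (3 and 3 adjusted over the list alone). The call of Pmvk ended without Control 2 (adjusted p 0.0635), Control 3 (0.0809), Control 4 (0.0754), T2MG 1 (0.118) or T2MG 4 (0.0542). Of 17 glycolysis genes (median 0.12, mean -0.1, test downwards, adjusted p 0.197), 3 rose and 5 fell (3 and 5 adjusted over the list alone). The glucose transporter Slc2a1 (-2.13, adjusted p 8.71e-08), Hk2 (-1.71, adjusted p 3e-07), Slc16a3, Pfkfb3 and, chosen after its value was seen, Hif1a (-0.52) fell, and Pfkp (1.88, and 3.22 without Control 1), Tpi1 and Gpi1, chosen likewise, rose. The call of Hif1a ended without Control 2 (adjusted p 0.0617), Control 3 (0.0894), Control 4 (0.0619), T2MG 1 (0.0772), T2MG 2 (0.0777) or T2MG 3 (0.0561).

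Of 20 immediate early genes at P60 (median -0.2, adjusted p 0.206), 6 fell, among them Egr1 (-2.25, adjusted p 2.36e-05), and Klf6 (1.21) and, chosen after its value was seen, Ier3 rose (6 and 2 adjusted over the list alone). Of 14 growth factors (median 0.27, or 0.96 without P60 Control 1, adjusted p 0.206), 6 rose, among them Gas6 (1.82, adjusted p 3.2e-06), and Csf1 fell (-2.67, adjusted p 3.97e-06, 6 and 1 adjusted over the list alone). Lyz1 (2.64, and 3.99 without P60 Control 1) rose among 15 monocyte markers (median 0.18, adjusted p 0.559, 1 adjusted over the list alone), a list that was called without P60 Control 1 (2.21, 0.00192). Cd4 (6.25, and 9.6 without P60 Control 1) rose among 17 lymphocyte markers (median -0.64, mean -0.32, test upwards, adjusted p 0.6, 1 adjusted over the list alone), a list also called without that library (3.43, 0.00167). Among 11 neutrophil markers (median -2.53, adjusted p 0.197, but 1.24, 0.685 without P60 Control 1), Mmp9 rose (4.79, and 8.26 without P60 Control 1) and Csf3r (-2.21, adjusted p 8.46e-08) and Cxcr2 (-1.62, adjusted p 0.0499) fell (1 and 1 adjusted over the list alone). The call of Cxcr2 ended without P60 Control 1 (-0.85, adjusted p 0.271), Control 3 (0.0652), T2MG 2 (0.0954), T2MG 3 (0.114) or T2MG 4 (0.122). Itm2a (2.24, and 2.94 without P60 Control 1) and Egfl7 (1.14) rose among 17 endothelial markers (median 0.17, or 0 without 3 members at or under the floor in both groups and 1.39 without P60 Control 1, adjusted p 0.874, 1 adjusted over the list alone). Egfl7 lost its call without Control 3 (adjusted p 0.0863), Control 4 (0.0793), T2MG 2 (0.0662) or T2MG 3 (0.0876). Alas2 (1.82, adjusted p 0.0101) and Hemgn (2.31) rose among 7 erythroid genes (median 1.82, or 2.01 without 2 such members, adjusted p 0.359, 3 adjusted over the list alone). Hemgn had 3.72 without Control 1 and lost its call without Control 2 (adjusted p 0.0638), Control 3 (0.0621), Control 4 (0.063) or T2MG 1 (0.131).

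A fit of only the P60 libraries called 5658 genes, 2720 higher and 2938 lower, a share of 48.1% higher against 60% in the fit of all libraries, and a fit with the neuron list as a covariate called 2657. Over the 3 stages, the list calls that held with an estimated correlation were homeostatic microglia at each stage, the TGF-beta pathway at P15 and P60, and border-associated macrophages at P60.

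**Figure D2:**
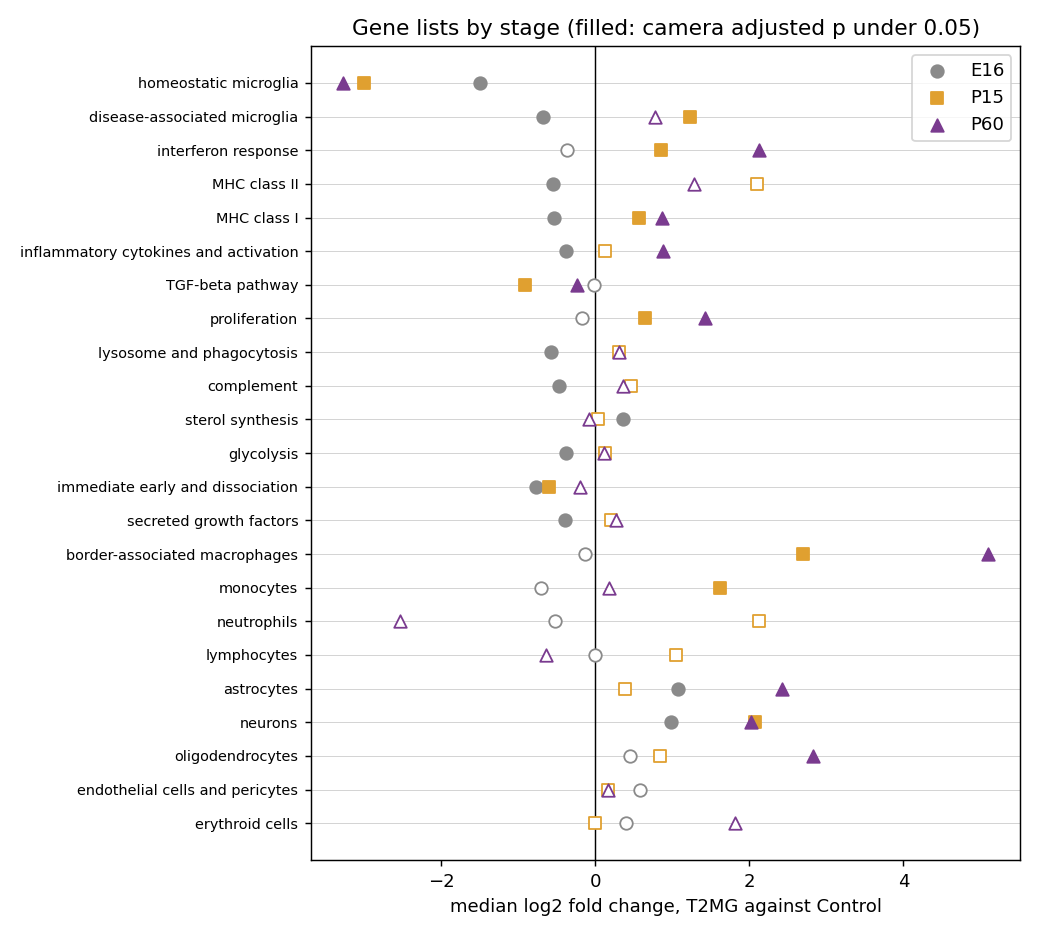
Median log2 fold change of T2MG against Control for each of the 23 gene lists at E16 (grey circles), P15 (orange squares) and P60 (purple triangles), with filled symbols for a camera adjusted p under 0.05. The homeostatic list lies at -1.49, -3 and -3.27 and the border-associated macrophage list at -0.13, 2.69 and 5.1.

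Differences of the genotype effect between stages were tested in the same model. From E16 to P15 the effect on Apoe moved up by 4.3 (adjusted p 2.88e-06), that on Spp1 by 5.58 (adjusted p 0.000213), that on Mrc1 by 3.63 (adjusted p 0.000852) and that on the lysosomal glycoprotein Gpnmb by 6.33 (adjusted p 0.000645). The effect on Smad7 moved by -3.05 (adjusted p 0.0019). That on Tmem119 (-0.81, adjusted p 0.53) was not called. In all 2534 genes differed, 1396 upward and 1138 downward, 1795 of them at least 2-fold. This count was 1411 without E16 Control 1 and 1681 without P15 Control 3.

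From P15 to P60 the effect on Il10 moved by 6.2 (adjusted p 4.31e-06), that on Gpnmb by -6.51 (adjusted p 0.000986) and that on Sall1 by -3.75 (adjusted p 0.00935, and -3.03 without P15 T2MG 2). Apoe (0.63, adjusted p 0.207) was not called. In all 1249 genes differed, 876 upward and 373 downward, 1005 of them at least 2-fold, and the median of all genes was 0.115 (0.037 with RLE). Upward genes made 70.1%, or 59.9% with RLE size factors. The count was 580 without P15 Control 3, 758 without P15 Control 1, 802 without P60 T2MG 4 and 2665 without P60 Control 1. From E16 to P60 the effect on Apoe moved by 4.93 (adjusted p 9.7e-08), that on Mrc1 by 5.26 (adjusted p 8.2e-06) and that on Adgrl3 by 6.9 (adjusted p 0.000254). The effects on Adgrg1 (-6.83, adjusted p 5.35e-07) and Smad7 (-3.62, adjusted p 0.000125) moved down. In all 3148 genes differed, 1922 upward and 1226 downward, 2231 of them at least 2-fold, with a median of all genes of 0.152 (0.047 with RLE). Upward genes made 61.1%, or 51.6% with RLE size factors (1628 upward and 1526 downward).

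In Control libraries, Tmem119 and Smad7 were higher at P15 than at E16, and Apoe, Mrc1 and Mki67 were lower. Tmem119 rose by 3.81 (adjusted p 0.000136) and Smad7 by 2.87 (adjusted p 2.22e-05). Mrc1 fell by 3.71 (adjusted p 5.4e-06), from 960 ± 53.9 to 73.5 ± 12.8 CPM, Apoe fell by 1.44 (adjusted p 0.000101) and Mki67 fell by 2.89 (adjusted p 0.000862). The microglial genes Sall1 (0.71, adjusted p 0.238) and Cx3cr1 (1.33, adjusted p 0.0588) were not called. Among the largest rises were Slc47a1 (at least 342-fold), the T cell gene Cd3e (at least 284-fold), Gimap3 (at least 274-fold) and Kl (9.8, adjusted p 1.81e-05), a choroid plexus gene. Among the largest falls were Mir6236 (at least 6430-fold), Mir6240 (at least 3360-fold), the neuroblast gene Dcx (at least 1240-fold), Igf2bp1 (at least 993-fold) and the embryonic globin Hbb-y (ratio 5850, 95% interval 1050 to 231000). The fitted log2 fold change of Hbb-y was -11.96, or -13.64 without P15 Control 2. Of 15568 genes, 3739 were higher and 4157 lower at P15, 7896 in all, 5198 of them at least 2-fold. With the neuron list as a covariate 1358 were called.

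From P15 to P60, Zfp488 (2.33, adjusted p 0.000354) and Wdfy1 (2.83, adjusted p 0.00588) rose in Control libraries, and Igfbp5, a growth factor binding protein (-6.22, adjusted p 4.35e-05), and Ear1 (-5.88, adjusted p 0.000169) fell. Tmem119 (0.72, adjusted p 0.369) and Apoe (-0.25, adjusted p 0.427) were not called. Of 15568 genes, 874 were higher and 2019 lower at P60, 2893 in all, 1816 of them at least 2-fold. The count was 4944, 1644, 1695 and 1663 without P60 Control 1, 2, 3 and 4, and 1293 and 1513 without P15 Control 1 and 3.

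Genotype effects were set against changes between stages in Control libraries that did not enter them. Across 15568 genes, which are not independent replicates, the P60 genotype effect and the Control change from E16 to P15 had a Pearson r of -0.232 (Spearman rho -0.242). The P15 genotype effect and the Control change from E16 to P60 had -0.154 (rho -0.22). The E16 genotype effect and the Control change from P15 to P60, a relation chosen after the data were examined, had -0.249 (rho -0.24), or -0.154 and -0.152 without E16 Control 2 and T2MG 1. The first was -0.129 without P60 Control 1 and the second -0.067 without P15 T2MG 2, and the jackknife SE over libraries was 0.114, 0.105 and 0.164 for the 3 relations. Genes higher in Control at P15 than at E16 and lower in T2MG at P60 numbered 1090 (588 for independent lists), and genes lower in that Control change and higher in T2MG 1345 (979). For the P15 genotype effect and the Control change from E16 to P60 these counts were 1082 (501) and 825 (626), and for the E16 effect and the change from P15 to P60 83 (23) and 8 (11).

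Between stages, P15 and P60 shared 1256 higher genes (429 for independent lists) and 1192 lower genes (301), with no library in common. E16 and P15 shared 27 (10) and 210 (51), and E16 and P60 shared 34 (19) and 267 (65). At all 3 stages, 24 genes were called higher and 204 lower. Across genes, which are not independent replicates, the Pearson r of effects was 0.387 for E16 and P60 (Spearman rho 0.308) and 0.444 for P15 and P60 (rho 0.414). For E16 and P15 the coefficients differed in sign, with an r of 0.095 and a rho of -0.04.

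**Figure D3:**
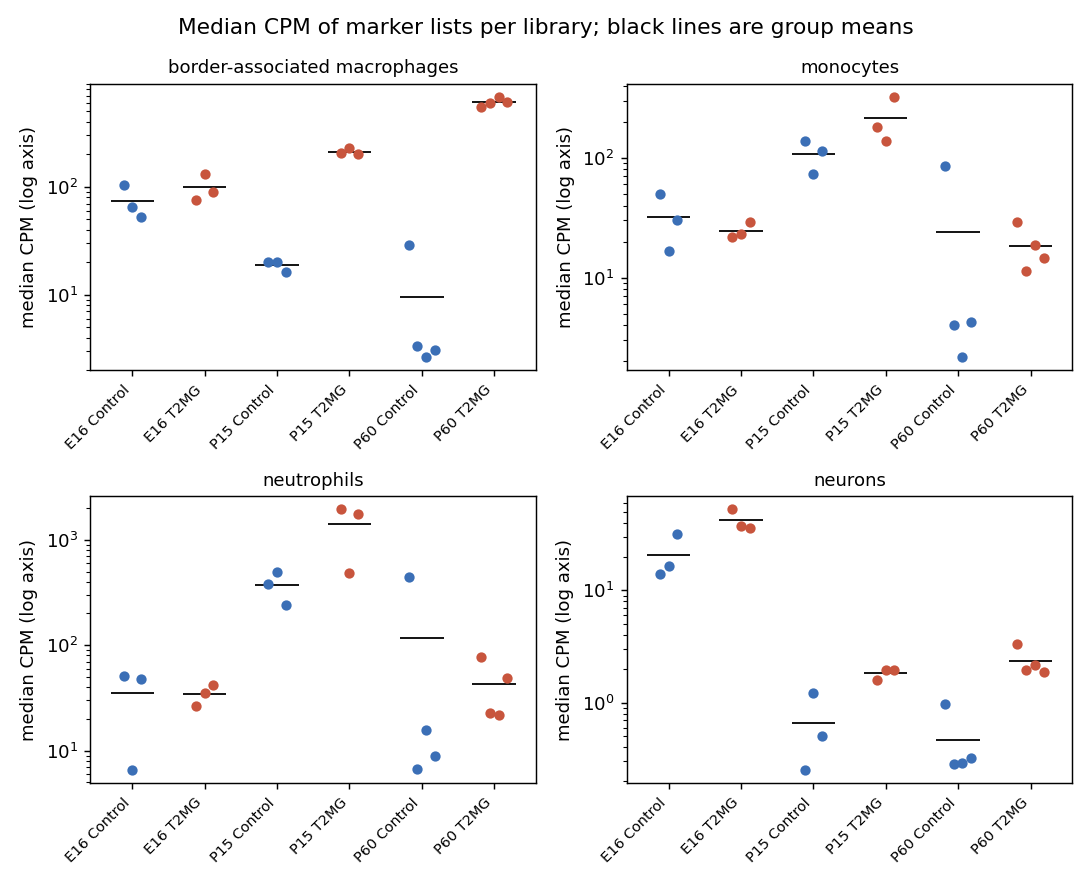
Median level of the border-associated macrophage, monocyte, neutrophil and neuron lists in each library, in CPM on a log axis, for Control (blue) and T2MG (red) at each stage. The neutrophil median is 439 CPM in P60 Control 1, and the border-associated macrophage list is higher in every T2MG than in any Control library at P15 and P60.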

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

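The test of leukocyte genes at E16 and the other splits of the libraries were chosen before their results were seen. Chosen after were the tests of P60 Control 1, of border-associated macrophages and of scaling at P60. Splits that keep the genotypes of the later stage apart and regroup the earlier stage were also chosen after.

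P60 Control 1 lay far from the other 3 P60 Control libraries in 19 of 67 measures, by the gap to the nearest library over the range of the group, which chance alone exceeds in about 1 of 20 groups. Its list medians were 215 CPM for disease-associated microglia, 217 for MHC class I, 33.7 for proliferation, 33.5 for sterol synthesis, 29.1 for border-associated macrophages, 85.6 for monocytes, 439 for neutrophils, 22.9 for lymphocytes, 0.97 for neurons and 7.21 for erythroid cells. Its gene levels were 202 CPM for Axl, 86.5 for Clec7a, 599 for H2-Ab1, 1940 for Cd74, 143 for Ccr2, 0.139 for Mrap, 7.14 for Mmp13, 17.6 for Clec4n and 0.554 for C6. In P60 T2MG 1 the erythroid median was 29.4 CPM, Siglech 38.2 CPM and Cx3cr1 660 CPM, and in P60 T2MG 3 Adamts16 was at 0.234 CPM, 4 of 67 measures in that group.

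RNA of other leukocytes and a P15 Control library under a P60 label cannot be told apart as sources of the position of P60 Control 1, since its medians of monocyte, neutrophil and lymphocyte genes were 20.2, 27.9 and 71.4 times those of the highest other P60 Control, but P15 Controls had 72.6 to 138, 242 to 497 and 5.75 to 18 CPM, against 85.6, 439 and 22.9 here. Of abundant genes of these cells, Ngp was at 2620 CPM against at most 33.9 in the other P60 Controls and 906 to 2670 in P15 Controls, S100a8 at 1240 against 30.4 and 371 to 1180, Ltf at 1180 against 15.7 and 462 to 1270, Chil3 at 1110 against 23.4 and 528 to 1360, Lyz1 at 363 against 73.7 and 421 to 525, Ly6c2 at 174 against 3.28 and 40.2 to 135, Nkg7 at 91.9 against 1.68 and 28.2 to 75, Lck at 57.2 against 0.923 and 10.6 to 50.5 and Cd79b at 99 against 81 and 43 to 51.2. Of the list members, 4 of 15 monocyte, 4 of 11 neutrophil and 1 of 17 lymphocyte genes also reached 10 CPM in each other P60 Control, and the gates of the sort are not given in the sources used here. Over 4944 genes, those called between the P15 Controls and the other P60 Controls, the library lay at 0.71 on a scale from P60 (0) to P15 (1), where the other P60 Controls lay at -0.01 to 0.04 and the P15 Controls at 0.84 to 1.12. No biological explanation was tested for it.

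At E16 the homeostatic list was lower in T2MG and the neuron and astrocyte lists higher, the last 2 with adjusted p 0.2 with an estimated correlation. The median log2 fold change was -1.49 for the homeostatic list and -0.54 for 20 genes that leukocytes in general express (8 called). The gap was -0.95 (bootstrap SE 0.22 over genes, 10000 resamples). More non-leukocyte RNA would lower both alike. The SE takes genes as independent (estimated correlation 0.492 in the homeostatic list) and omits variation between libraries, so a smaller microglial share stays open. More RNA of other leukocytes could spare the 20 genes. A change of microglia by the genotype stays open and was not tested.

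At P60 the border-associated macrophage list was higher and the homeostatic list lower in T2MG. Scaling moved by a few abundant genes would move both lists alike, which they did not. The gap of median log2 fold changes, 8.37 (bootstrap SE 0.93 over genes), restates the pattern and is no separate test. Border-associated macrophages in place of microglia stay open as a candidate explanation, because no library here holds such cells alone and 6 of the 20 (Ccr1, Cp, Lyz2, Mrc1, Ms4a6c and Stab1) reached 10 CPM in each other P60 Control. The calls of 19 of 20 list members are the pattern itself and no support for it. The level left in T2MG, as a percentage of Control, was 0.215 for Sall1, 0.827 for Olfml3, 1.26 for Tmem119, 1.38 for P2ry12, 1.6 for Siglech, 7.48 for Gpr34 and 12.3 for Cx3cr1. A change of microglia themselves by the genotype stays open and was not tested.

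Chance can be excluded for the count of genes at P60, where 1 of 35 splits of the 8 libraries, the real one, gave 6113 genes and the highest other 1345. For the difference between P15 and E16, 1 of 33 splits drawn from 200, the real one, gave 2534 genes and the highest other drawn 519. That other split kept the P15 genotypes apart. Splits of both stages also mix the genotypes within P15, so a genotype effect at P15 alone could give this result. They do not exclude chance for the difference. For P60 against P15 (1249 genes) and against E16 (3148), 2 of 33 splits drawn from 700 gave as many. These counts alone do not exclude chance. Drawn splits that mixed P60 genotypes gave at most 4 and 0. With the later stage's genotypes kept apart, 0 (P15 and E16), 15 and 4 of 19 other splits gave as many (up to 2075, 6593 and 4298). In Control libraries of P60 against P15, 2 of 35 splits gave as many genes (2893 against 4713), and the larger put P60 Control 1 with the P15 Controls. The 10 splits at E16 (498 genes, highest other 0), at P15 (3738, highest other 1) and of Control P15 against E16 (7896, highest other 0) are too few for a share under 0.05.

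The genotype effect differed between P15 and E16 for 2534 genes by the interaction term of edgeR. As log2 differences of the effects, P15 less E16, there were Ebf3 (-10.01, and -10.69 without E16 Control 3), Zswim5 (-6.22, and -9.66 without P15 T2MG 2), Nes (-6.14, and -7.97 without P15 T2MG 3), Gpnmb (6.33), Spp1 (5.58), Apoe (4.3), Mrc1 (3.63) and Smad7 (-3.05). Col6a3 had -6.35, or -7.23, -9.47 and -5.75 without E16 Control 3, P15 T2MG 1 and P15 T2MG 2. Gdf15 had 7.88, or 7.29 and 6 without E16 Control 1 and P15 T2MG 3. BC100530 had 7.8, a call that ended without P15 T2MG 3 (4.44, adjusted p 0.0618). Il1r2 had 6.64, a call that ended without E16 Control 1 (adjusted p 0.0539) or P15 T2MG 3 (3.5, 0.0661). H2-M2 had 5.79, a call that ended without E16 Control 1 (4.95, adjusted p 0.211), E16 Control 2 (0.0557), E16 T2MG 1 (0.0657), E16 T2MG 2 (0.0618), P15 Control 2 (0.0515) or P15 Control 3 (0.0615), with 6.46 without E16 T2MG 3 and 6.88 without P15 Control 1.

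Between P60 and P15 the effect differed for 1249 genes. As log2 differences, P60 less P15, there were Il10 (6.2), Gpnmb (-6.51), Ptprk (5.48), Cxcl1 (5.45) and Cd55 (5.02), the last 3 with 7.06, 6.53 and 6.03 without P60 Control 1. Ifi202b had 8.66, or 7.74 and 9.36 without P15 Control 1 and P15 T2MG 2, Sall1 -3.75, or -3.03 without P15 T2MG 2, and Cst7 -3.86, or -5 without P60 T2MG 1. Il1b had 2.38, not called without P15 Control 1 (adjusted p 0.0502) and 3.01 without P60 Control 1. Lrg1 had -7.03, not called without P15 Control 3 (0.0527), with -5.8 without P15 T2MG 3 and -3.47 without P60 Control 1. Spp1 had -2.41, a call that ended without P15 Control 1 (0.0632), P15 Control 3 (0.0912), P15 T2MG 3 (0.085), P60 Control 3 (0.0563), P60 Control 4 (0.0503) or P60 T2MG 2 (0.0578). BC100530 had -7.14, a call that ended without P15 Control 1 (0.0705), Control 2 (0.0556), Control 3 (0.0766), P15 T2MG 3 (-3.78, 0.132) or P60 Control 3 (-6.2, 0.0585), and -8.22 without P60 T2MG 4. Mmp8 (-6.25) and Wfdc21 (-5.58) lost their calls without P15 Control 1 (0.0699 and 0.0747), Control 2 (0.0646 and 0.0724), Control 3 (0.0925 and 0.109), P15 T2MG 3 (-4.75, 0.0844, and -5.03, 0.0796), P60 Control 1 (-2.41, 0.0848, and -1.95, 0.183), P60 T2MG 2 (0.0562 and 0.0707), T2MG 3 (0.0547 and 0.0728) or T2MG 4 (0.0581 and 0.0675), and Wfdc21 without P15 T2MG 1 (0.0595).

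Between P60 and E16 the effect differed for 3148 genes. As log2 differences, P60 less E16, there were Adgrl3 (6.9), Adgrg1 (-6.83), Mlph (-7.94), Mrc1 (5.26), Apoe (4.93), Smad7 (-3.62) and Spp1 (3.17). Without P60 Control 1, Pf4 had 8.78 in place of 7.22, Cbr2 8.35 in place of 6.89 and Il1b 4.29 in place of 3.67. Without E16 Control 2, Sall1 had -6.7 in place of -6 and Tgfbr1 -3.19 in place of -2.6. Ebf3 had -10.1, or -10.79 without E16 Control 3, Atp8a2 -7.83, or -8.48 without P60 T2MG 1, Tspan18 -7, or -7.73 without P60 T2MG 2, and Il10 7, or 6.02 and 7.65 without E16 Control 1 and 3. Mki67 had 2.63, a call that ended without E16 Control 2 (adjusted p 0.0504), E16 T2MG 1 (0.0501) or E16 T2MG 2 (0.0661), and 3.76 without P60 Control 1. Cd209f had 6.97, a call that ended without E16 Control 1 (0.0545), E16 Control 2 (5.99, 0.186), E16 T2MG 1 (0.057) or E16 T2MG 3 (0.0655), with 7.72 without E16 T2MG 2 and 10.38 without P60 Control 1.

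Of 27 entries with a date in place of a symbol, kept out of the comparisons, 22 could be tested, and 5 were called at P15 (3 higher, 2 lower) and 9 at P60 (7 higher, 2 lower).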

How the results depend on the processing

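The covariates and the fit without P60 Control 1 and P15 T2MG 3 were chosen after the results were seen. Of 575 gene results 325 kept their direction and their side of the threshold under every alternative run, and of 11205 values 10289 did, 646 lost a call, 264 gained one and 6 reversed. Of 69 list results 21 kept both, and of 1194 values 1080 did, 60 lost a call, 52 gained one and 2 reversed. Where a result changed, the cause was not tested. DESeq2 gave a value for 556 of the 575 gene results and the CPM filter for 574. Counts of called genes under RLE size factors, both filters and the robust fit stayed within 1.5 times those reported.

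At E16, 498 genes became 986 with DESeq2, 1198 with limma voom, 319 with only the libraries compared and 125 with the neuron covariate. Leaving out 1 library gave 148 to 961. At P15, 3738 became 2209 with only the libraries compared, 2395 with the neuron covariate and 3836 without the 2 libraries named above, and leaving out 1 library gave 2470 (without Control 3) to 4086. At P60, 6113 became 2657 with the neuron covariate and 7946 without the 2 libraries, and leaving out 1 gave 5199 to 7354. The difference between P60 and P15 (1249) became 2288 with DESeq2, 1882 with limma voom and 712 with only the libraries compared. It became 801 with the Xist and 2357 with the neutrophil covariate, 2663 without the 2 libraries and 580 to 2665 without 1 library. That between P60 and E16 (3148) became 5190 without the 2 libraries and 2301 to 4507 when 1 was left out. That between P15 and E16 (2534) became 1411 to 3191 when 1 was left out. Control P15 against E16 (7896) became 1358 with the neuron covariate and 6560 to 7304 when 1 was left out. Control P60 against P15 (2893) became 1118 with only the libraries compared, 516 with the neutrophil covariate and 5667 without the 2 libraries. Leaving out 1 gave 1293 to 4944.

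Of the gene lists, 13 were called at E16, 1 with an estimated correlation and 11 to 16 when 1 library was left out. At P15 10 were called, 5 with the neuron covariate, 16 without the 2 libraries, 2 with an estimated correlation and 6 with fry, and 6 (without Control 2) to 11 when 1 library was left out. At P60 10 were called, 3 with an estimated correlation and 10 to 13 when 1 library was left out. With fry the calls of both MHC lists at E16 and of interferon, MHC class I, proliferation, immediate early and monocyte genes at P15 ended. The correlation across genes of the P60 genotype effect with Control P15 less E16 (-0.232) stayed between -0.29 and -0.129, and that of the P15 effect with Control P60 less E16 (-0.154) between -0.257 and -0.067. Genes called higher at both E16 and P15 numbered 27, or 76 with DESeq2, and at both E16 and P60 34, or 123 with DESeq2. The neuron covariate is the mean of the neuron list, so it removes the effect of that list and its members by construction, and the turned signs of the list at E16 (-0.26) and P60 (-0.04), the 2 reversals above, and of Map2 at P15 (-0.05) say nothing of stability. With it the sign also turned for Csf1r in Control P15 against E16 (-0.24). At P60, Cd8a (-3.39, not called) and Nkg7 (-1.77, not called) became 2.82 and 2.55 without P60 Control 1, and also without the 2 libraries, and when 1 library was left out their lowest values were -4.14 and -2.19.

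Replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at 0.007 to 0.333 at E16, -0.034 to 0.133 at P15 and -0.063 to 0.224 at P60, and those with different numbers at -0.294 to 0.274, -0.129 to 0.125 and -0.249 to 0.19. With the replicate number as a block, the genotype counts were 276, 3284 and 6033 at E16, P15 and P60, those of differences between stages 2031, 907 and 2956, and those of Control comparisons 7871 and 2802. Of simulated 2-fold changes 36% were recovered at E16, 36% at P15 and 56% at P60. Changes of this size can be missed at each stage, and E16 libraries were shallower than the others.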

Other observations

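The genes in this paragraph come from the choice fixed before the data were examined and were picked from it after their values were seen. Levels are means ± SD (n = 4 per group at P60). At P60, Siglech fell by 5.96 (SE 0.59, adjusted p 4.18e-07), from 1340 ± 351 to 21.5 ± 11.2 CPM. Tgfb1, a ligand of the targeted receptor, was not called at E16 (-0.01, adjusted p 0.995), P15 (-0.22, adjusted p 0.606) or P60 (0.14, adjusted p 0.682), but at P15 it had -0.86 (adjusted p 0.00453) without P15 T2MG 1.

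The Y-linked gene Ddx3y, chosen after its values were seen, stood at 42.8 CPM in E16 T2MG 2, 47.4 and 50.5 CPM in P15 T2MG 1 and 3, 57.5 and 116 CPM in P60 Control 2 and 3, and 103 and 109 CPM in P60 T2MG 3 and 4, and at 1.11 CPM or less in each other library.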
